A study of Mus musculus with 24 samples.

How the data were processed

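RNA from mouse liver was sequenced after oligo-dT selection of polyadenylated transcripts, per the labels' protocols. The labels name 4 groups of 6 libraries: floxed control and liver Gpt2 knockout mice, each fed ad libitum or fasted for 18 h. The library is the replicate, and the groups were taken from the sample titles. The files gave, for each of 41388 Ensembl genes in GRCm38 coordinates, a gene length and 3 values. Per the submitters' processing notes, the deposited read counts per gene were made with bcl2fastq (version not given in the sources used here), STAR 2.5.1a and featureCounts 1.4.6-p5 of Subread. The deposited CPM values, per the file headers and as checked against the counts, were each count divided by the library's total and carried no scaling factor. The deposited RPKM values, per the file headers and as checked, were CPM per kilobase of the length column. The counts entered every test, and deposited CPM and RPKM served only as a check of them. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and reads of close paralogs are uncertain.

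Gene symbols came from GENCODE M21, whose GRCm38 annotation held 40340 of the genes; in all 40254 genes (97.3%) received a symbol, with 8 symbols used by more than one gene. Of the genes found, 99.9% overlapped the position given there and 76.1% had the same start and end. The file of control fed replicate 6 was damaged: of 978 lines 964 were complete, all on chromosome 1, and it was left out, so that 23 libraries were used. Total reads assigned to genes had a median of 29.2 M in control fed (27.7 to 40.0 M, n = 5), 40.9 M in control fasted (19.9 to 46.5 M, n = 6), 34.05 M in knockout fed (23.0 to 44.5 M, n = 6) and 46.45 M in knockout fasted libraries (18.4 to 55.3 M, n = 6). No pair of libraries within a group was a duplicate, and pairs across groups were not compared: over 55 pairs within groups the chi-square per degree of freedom, over genes with at least 20 reads in the pair, lay between 37.4 and 1760.

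Counts were tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood fit (glmQLFit and glmQLFTest), with TMM factors and filterByExpr by group (minimum count 10, minimum total 15). All 4 groups entered 1 fit without covariates, which gave the genotype effect in each feeding state and averaged over them, the fasting effect in each genotype, and the interaction. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, and standard errors were the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, and logarithms of them used a prior count of 2. Gpt2 and Gpt were also compared by two-sided exact permutation tests of log2 CPM. All results were computed over the 23 libraries and again over 22, without the library labelled control fasted replicate 4.

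The genes named were Gpt2 and Gpt. For each contrast they were also the 10 highest and the 10 lowest fold changes among called genes with a mean log2 CPM of at least 2 (5 and 5 for fasting in knockout mice), without predicted genes, pseudogenes and genes without a symbol. For each list described, up to 4 members with the smallest p were named. Where fewer than 5 genes passed in a genotype contrast or the interaction, the 5 smallest p were named as not passing. Some genes that these rules take are not reported here. The 35 gene lists held 557 distinct matched members, of which 25 stood in more than one list, and 1 further member was not matched. They covered carbohydrate, amino acid, lipid and bile acid metabolism, hormonal and stress responses, the clock, cell division, liver zonation and other cell types. Each list was tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, again with an estimated correlation, and with fry.

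The alternatives were RLE factors, library totals, no filter beyond 1 count, a mean CPM of at least 1, DESeq2 1.42.0, limma voom with sample weights, only the groups compared, mitochondrial and the 20 most abundant genes left out, clusters of title numbers as a random block, and each library left out in turn. For lists they were also an estimated correlation, library totals, RLE factors and the removal of members shared with another list.

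The procedure was tested on simulated counts drawn from the levels of the real genes, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each comparison. Of genes changed 1.5-, 2- and 4-fold it recovered 26.9%, 55.2% and 62.1% for the genotype effect in fed mice (16097 genes), 17.9%, 44.8% and 69.7% in fasted mice (16037 genes) and 35.8%, 47.8% and 72.7% for the averaged effect (16082 genes). For fasting it recovered 17.9%, 46.3% and 66.7% in control mice (16069 genes) and 17.9%, 41.8% and 68.2% in knockout mice (15971 genes), and for the interaction 3%, 17.9% and 50% (16010 genes). Genes simulated without a change made up 9 of 132 calls (6.82%) for the genotype effect in fed mice, 5 of 115 (4.35%) in fasted mice and 8 of 167 (4.79%) for the averaged effect. They made up 5 of 111 calls (4.5%) for fasting in control mice, 4 of 108 (3.7%) in knockout mice and 1 of 53 (1.89%) for the interaction. In each comparison 5 of 5 shifted lists were called and 0 of 25 unchanged lists, by camera at the preset correlation. The simulation used the 22 libraries and drew each gene independently. It therefore says nothing on false calls of lists whose genes move together.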

Results

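Liver RNA was sequenced from mice in a factorial design of 4 groups. Control mice carried a floxed Gpt2 gene and knockout mice were labelled as liver knockouts of this gene, which encodes alanine transaminase 2. Each genotype was either fed ad libitum or fasted for 18 h before sampling. The labels name 6 libraries in each group, 24 in all. The file of control fed replicate 6 held 964 complete gene lines, all on chromosome 1, and was not used, which left 5 control fed libraries and 23 libraries in total. They held between 18.4 M and 55.3 M reads assigned to genes. The comparisons ask how the liver transcriptome differs between genotypes in each feeding state, how it changes with fasting in each genotype, and whether that change differs between genotypes. The labels do not say that each library came from a separate animal, so p-values measure only the spread between these samples.

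The targeted gene was examined first in every library, in CPM (reads of a gene per M reads assigned to genes) scaled by TMM factors. Gpt2 encodes the mitochondrial alanine transaminase, which interconverts alanine and pyruvate. It lies on the forward strand of chromosome 8 from 85492576 to 85527560 in GRCm38. The counts are per gene, so reads from exons that were not deleted still count. In fed mice Gpt2 stood at 379 ± 51.9 CPM in control livers (SD, n = 5, range 316 to 456) and at 61.8 ± 11.8 CPM in knockout livers (SD, n = 6, range 48.6 to 79.9), 16.3% of the control mean. The ranges did not overlap, and the exact two-sided permutation test of log2 CPM gave p = 0.00216, the smallest value that its 462 arrangements allow. In fasted mice 5 control libraries lay between 570 and 817 CPM (715 ± 90 SD, n = 5). The knockout libraries lay between 53.5 and 151 CPM (114 ± 37.2 SD, n = 6), 16% of that control mean, with an exact permutation p = 0.00216. The sixth, the library labelled control fasted replicate 4, held 33.8 CPM, below every knockout library and against its label. With it the control mean was 601 ± 289 CPM (SD, n = 6) and the exact permutation p = 0.0195. Gpt, the cytosolic alanine transaminase gene (chromosome 15, 76696764 to 76699674), was at 409 ± 56.3 CPM in control fed (SD, n = 5) and 323 ± 20.6 CPM in knockout fed livers (SD, n = 6), with an exact permutation p = 0.00216. Across all genes this difference did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (log2 -0.34 ± 0.13 SE, adjusted p = 0.409 over 22 libraries). In fasted mice Gpt was at 307 ± 41.9 CPM in control (SD, n = 5) and 320 ± 73.6 CPM in knockout livers (SD, n = 6), 104% of the control mean, with an exact permutation p = 0.859. With the library labelled control fasted replicate 4 the control mean was 260 ± 123 CPM (SD, n = 6) and the exact permutation p = 0.429.

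**Figure D1:**
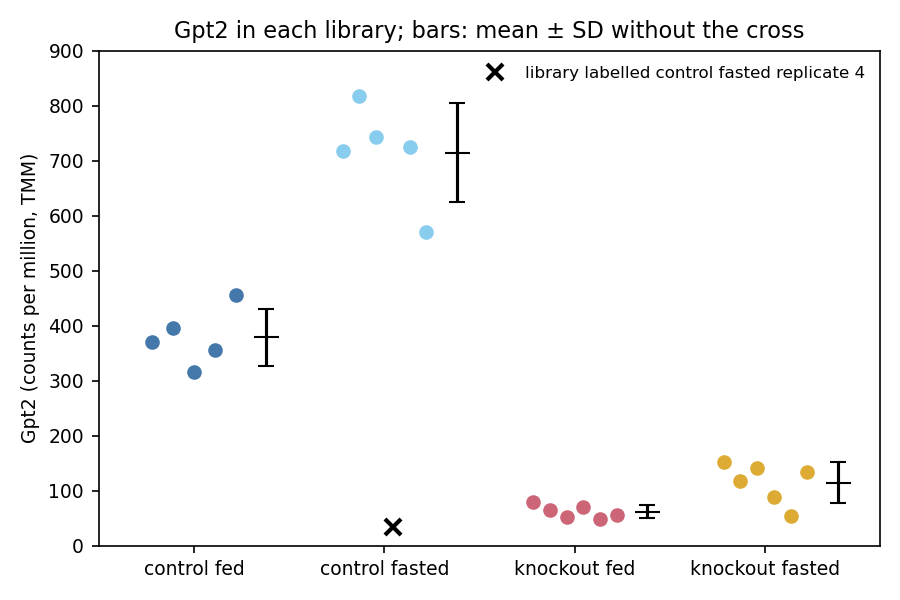
Gpt2 in CPM (vertical axis, linear, scaled by TMM factors) in each of 23 libraries by group; points are libraries, the cross is the library labelled control fasted replicate 4, and bars give mean ± SD without it. Knockout libraries lie between 48.6 and 151 CPM, control libraries between 316 and 817 CPM, and the cross is at 33.8 CPM.

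The library labelled control fasted replicate 4 differed from the other 22 libraries in its tissue-specific genes. Albumin (Alb), among the most abundant transcripts of hepatocytes, had 5307 reads there (75.7 CPM), against group means of at least 63700 CPM in the other libraries. Kap, a gene of kidney proximal tubule, had 304704 reads there (4346 CPM) and at most 9.21 CPM elsewhere. For this reason the number of genes called in each contrast is given over all 23 libraries, as designed, and over the 22 libraries without it. Counts of genes changed at least 2-fold and of list members called are given over the 22 libraries. The fit of 22 libraries was chosen for the gene values given here after the data were seen. Leaving this library out also changed the number of calls in contrasts to which it does not belong.

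**Figure D2:**
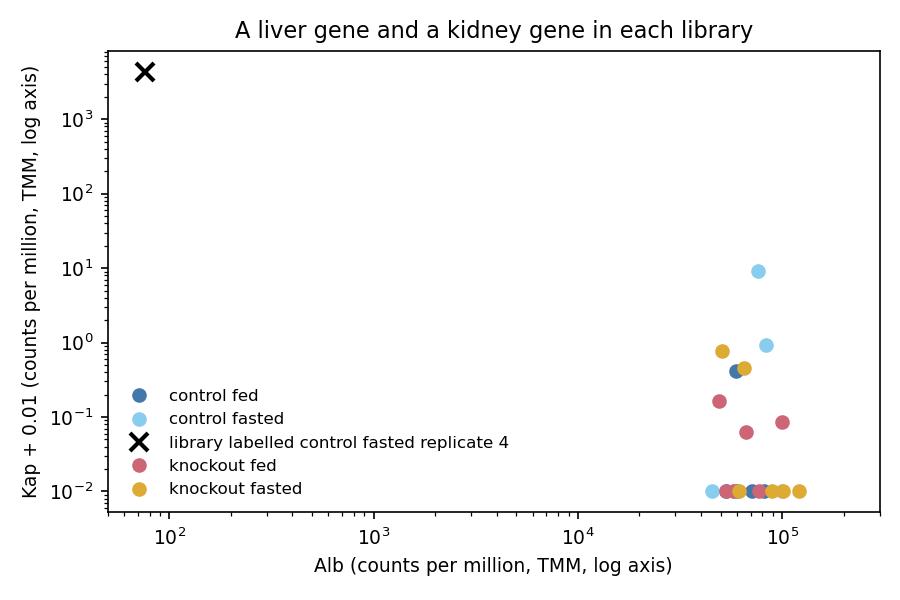
Alb (horizontal axis) and Kap (vertical axis), both in CPM scaled by TMM factors on log axes, in each of 23 libraries; libraries with no Kap read are drawn at the foot of the axis. The library labelled control fasted replicate 4 has 75.7 CPM of Alb and 4346 CPM of Kap, and no other library exceeds 9.21 CPM of Kap.

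Fasting of control mice raised transcripts of fatty acid catabolism and lowered those of lipid synthesis. Cyp4a14, a fatty acid omega-hydroxylase, went from 80 ± 78.2 CPM in fed to 5870 ± 1010 CPM in fasted control livers (SD, n = 5 and n = 5), a log2 fold change of 6.20 ± 0.74 (SE). Cpt1a, which admits long-chain acyl groups to mitochondria, rose from 246 ± 61.9 to 799 ± 68.1 CPM (1.70 ± 0.14). Thrsp, a regulator of lipogenesis, fell from 256 ± 153 to 12.5 ± 7.83 CPM (-4.38 ± 0.58) and Hsd3b5, a male-biased steroid dehydrogenase, from 201 ± 50.7 to 13.5 ± 7.21 CPM (-3.90 ± 0.56).

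Over all 23 libraries edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 805 of 17055 genes in this comparison, 426 higher and 379 lower. Over the 22 libraries it called 1360 of 16757 genes, 668 higher and 692 lower, of which 474 changed at least 2-fold (241 higher, 233 lower). Both fits called 711 of these genes. The greatest rises and falls given here are among called genes taken by the naming rule, with a mean log2 CPM of at least 2, and genes of lower level could change more. Besides Cyp4a14, the genes with the greatest rises over 22 libraries were Acot3 (log2 4.96 ± 0.82 SE), Cyp4a31 (4.45 ± 0.48), Cyp4a10 (4.40 ± 0.35), Gadd45b (4.32 ± 0.95), Acot1 (4.08 ± 0.39), Cyp17a1 (3.63 ± 0.96), Ehhadh (3.57 ± 0.34), Nipal1 (3.52 ± 0.73) and Acot2 (3.42 ± 0.43). Acot1, Acot2 and Acot3 are acyl-CoA thioesterases that lie in a cluster of close relatives, as do the Cyp4a genes, so their values are uncertain where reads were split between neighbours. The greatest falls were in Dmbt1 (-7.88 ± 2.35), Thrsp, Hsd3b5, Cyp2c55 (-3.80 ± 0.53), Clec2h (-3.77), Selenbp2 (-3.35 ± 0.47), Cyp2c70 (-3.34 ± 0.37), Gstm3 (-3.12 ± 0.32), Nudt7 (-2.87 ± 0.35) and Cyp26a1 (-2.76 ± 0.65). Dmbt1 rests on control fed replicate 3, which held 8857 reads, and without that library its log2 fold change was 1.48 (adjusted p = 0.757 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its call also ended without control fasted replicate 1, 2, 3, 5 or 6, knockout fed 2, 3, 4 or 5, or knockout fasted 3, 4, 5 or 6, at adjusted p of 0.0501 to 0.105 by the same edgeR test and Benjamini-Hochberg adjustment. The call of Cyp17a1 ended without control fed replicate 1, 2, 3 or 4 or control fasted replicate 2, and that of Clec2h without control fed replicate 4 or control fasted replicate 1, 2 or 5. Their adjusted p was then 0.0508 to 0.0709 by the same edgeR test and Benjamini-Hochberg adjustment. With limma voom with sample weights or with title-number clusters as a random block the calls of Gadd45b, Cyp17a1 and Clec2h ended (adjusted p = 0.1 to 0.163 after Benjamini-Hochberg adjustment). Dmbt1 then stood at -0.81 in both (adjusted p = 0.891 and 0.886, limma), and its call ended also with no filter beyond 1 count (0.0701) and with only the groups compared (0.192). The call of Nipal1 ended with the weights (0.0527), and that of Cyp26a1 with only the groups compared (0.0634, edgeR).

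Over all 23 libraries the genes with the greatest rises included several of kidney: Kap (log2 12.84 ± 3.26 SE), Fxyd2 (10.35 ± 2.82), Slc34a1 (10.11 ± 2.73), Napsa (9.83 ± 2.59), Gpx3 (9.43 ± 2.17), Egf (9.25 ± 2.52) and Acss1 (9.15). Slc22a12, Ggt1 and Npnt, for which the control fed libraries held 1, 3 and 0 reads in all, were also among the 10 greatest rises, and no fold is given for them. Without the library labelled control fasted replicate 4 Kap stood at 4.52 (adjusted p = 0.218), Fxyd2 at 2.27 (0.605), Slc34a1 at 1.78 (0.645), Napsa at 0.77 (0.868), Egf at 1.02 (0.772) and Acss1 at 2.20 (0.528) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Ggt1 lost its call (adjusted p = 0.14). The calls of these 7 genes and of Slc22a12 also ended without control fed replicate 1, 2, 3, 4 or 5, at adjusted p of 0.0559 to 0.105 by edgeR with Benjamini-Hochberg adjustment. Gpx3 stood at 2.09 without the library labelled control fasted replicate 4 and kept its call (adjusted p = 0.0279), as did Npnt (adjusted p = 0.000243), by the same edgeR test and Benjamini-Hochberg adjustment. The call of Gpx3 ended with limma voom with sample weights, title-number clusters as a random block or only the groups compared (adjusted p = 0.169 to 0.427), and that of Npnt with the latter pair (0.116 and 0.133). The calls of Acss1 and Egf ended without knockout fed replicate 5 or knockout fasted 2 (0.0501 to 0.0505), and that of Slc22a12 ended without knockout fed 5 (0.0628). Aqp8, an aquaporin, was among the 10 greatest falls in that fit (-2.92 ± 0.35). The count of 805 became 530 without control fed replicate 1 and 535 without control fed replicate 3. With library totals in place of TMM factors 66% of the calls over 23 libraries were higher, against 52.9%, and the median log2 fold change of all genes moved from 0.07 to 0.22.

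Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 35 lists. The values that follow are of the 22 libraries. Of the 24 other PPARA targets, 21 rose in fasted control livers and none fell (21 adjusted over the list alone), with a median log2 fold change of 2.45. Among them Acot4 rose by 2.33 ± 0.21, Crat by 2.56 ± 0.23 and Ehhadh by 3.57 ± 0.34 (SE). Of 19 genes of mitochondrial fatty acid oxidation and ketogenesis, 16 rose and none fell (16 and 1 adjusted over the list alone), with a median of 0.97. They included Cpt1a and Slc25a20 (1.31 ± 0.11), the carnitine carrier. Both lists passed camera (adjusted p = 4.39e-39 and 6.45e-31) and kept their call with an estimated correlation (adjusted p = 0.000413 and 0.00382). Fatty acid synthesis and targets of SREBP1c and ChREBP went the other way: 13 of 22 genes fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -0.72. This list passed camera (adjusted p = 7.61e-14, and adjusted p = 0.00449 with an estimated correlation). Acly (-1.67 ± 0.14), Acss2 (-1.85 ± 0.24) and Mid1ip1 (-1.97 ± 0.27) fell, whereas Elovl5, a fatty acid elongase, rose by 1.68 ± 0.15. Of 15 NRF2 targets, 4 fell and 2 rose (6 and 2 adjusted over the list alone), with Gstm3, Gstm1 (-1.25 ± 0.18) and Gsta4 (-1.33 ± 0.23) lower. This list passed too (camera adjusted p = 0.000225, and adjusted p = 0.0238 with an estimated correlation). Over 23 libraries 21 lists passed camera for this comparison, and 2 passed with an estimated correlation.

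The other lists that passed camera for fasting in control mice lost their call with an estimated correlation. Of 24 genes of cholesterol synthesis, 6 fell (10 adjusted over the list alone), with a median of -0.93, led by Ebp (-0.85 ± 0.12), Sc5d (-1.33 ± 0.24), Pmvk (-1.59 ± 0.30) and Dhcr7 (-1.33 ± 0.31), whose call ended with only the groups compared (adjusted p = 0.0696, edgeR with Benjamini-Hochberg adjustment). Camera gave this list an adjusted p = 1.23e-15, and adjusted p = 0.223 with an estimated correlation. In gluconeogenesis and pyruvate handling 4 of 18 genes rose and 1 fell, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00478; adjusted p = 0.243 with an estimated correlation). Pcx, pyruvate carboxylase, rose by 0.85 ± 0.14 and Mpc2, of the mitochondrial pyruvate carrier, by 0.68 ± 0.13, while Mdh1 fell (-0.45 ± 0.11). Of 18 growth hormone responsive and male-biased genes 3 fell, Ghr (-0.73 ± 0.12), Selenbp2 and Hsd3b5, and 6 adjusted over the list alone (camera adjusted p = 1.66e-05; adjusted p = 0.122 with an estimated correlation). Of 20 endoplasmic reticulum chaperones 6 were lower, also adjusted over the list alone, among them Pdia6 (-0.90 ± 0.19) and Sec61b (-1.03 ± 0.24). Their camera adjusted p = 2.57e-06, and adjusted p = 0.368 with an estimated correlation. In the acute phase list 7 of 22 genes fell and 3 rose, 9 and 4 adjusted over the list alone (camera adjusted p = 0.00394; adjusted p = 0.403 with an estimated correlation). Orm1 (-0.93 ± 0.14) and Fga (-0.61 ± 0.13) were lower and Lbp was higher (0.63 ± 0.12). Of 22 interferon stimulated genes 4 were lower, as adjusted over the list alone, including Bst2 (-1.06 ± 0.15) and Gbp7 (-1.04 ± 0.22) (camera adjusted p = 0.000462; adjusted p = 0.243 with an estimated correlation). Of 17 glycolysis and glycogen genes 2 were higher and 2 lower, 2 and 5 adjusted over the list alone (camera adjusted p = 0.00867; adjusted p = 0.368 with an estimated correlation). Ldha (1.41 ± 0.30) and Gys2 (0.70 ± 0.14) were higher and Pygl, glycogen phosphorylase, was lower (-0.95 ± 0.15). Of 22 insulin, FOXO and glucocorticoid responsive genes 1 rose, Fkbp5 (2.23 ± 0.34), and 4 adjusted over the list alone (camera adjusted p = 0.00175; adjusted p = 0.243 with an estimated correlation). Of 12 pericentral markers 4 fell and 1 rose, as adjusted over the list alone, with Cyp1a2 at -1.33 ± 0.16 and Lect2 at -1.13 ± 0.15 (camera adjusted p = 0.0387; adjusted p = 0.41 with an estimated correlation).

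Lists of other cell types also moved with fasting in control livers. Of 14 fibrosis and stellate cell markers 2 were lower, Col3a1 (-1.33 ± 0.22) and Col1a1 (-1.17 ± 0.32), as adjusted over the list alone (camera adjusted p = 0.0163; adjusted p = 0.25 with an estimated correlation). The call of Col1a1 ended without control fed replicate 5 or control fasted replicate 5 (adjusted p = 0.0933 and 0.0512 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and with limma voom with sample weights, title-number clusters as a block or only the groups compared (0.0533 to 0.0768). Kupffer cell and macrophage markers had a median of -0.32 with 0 of 13 called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.0391; adjusted p = 0.595 with an estimated correlation). Of the 10 exocrine pancreas markers 2 were tested and Cela1 fell (-2.29 ± 0.24; camera adjusted p = 0.0109; adjusted p = 0.122 with an estimated correlation).

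The remaining 19 lists did not pass camera for fasting in control mice, although genes in them changed. Of 29 genes of amino acid catabolism 2 were higher and 7 lower, 3 and 10 adjusted over the list alone (camera adjusted p = 0.281, direction down at a median of 0.00 and a mean of 0.01). Mat1a, which makes S-adenosylmethionine, rose by 1.66 ± 0.13 and Ido2 (-1.06 ± 0.13), Aldh4a1 (-0.73 ± 0.13) and Prodh (-1.13 ± 0.21) fell. Of 14 transaminases 2 were higher and 1 lower, 3 and 3 adjusted over the list alone (camera adjusted p = 0.825). Gpt2 rose by 0.91 ± 0.20 (n = 5 and n = 5), Kyat1 fell (-0.58 ± 0.13), and Gpt stood at -0.42 ± 0.14 without passing (adjusted p = 0.0517 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Urea cycle genes split, with Slc25a13 (0.67 ± 0.10) and Asl (1.24 ± 0.20) higher and Otc lower (-0.71 ± 0.12), the same 3 of 8 as adjusted over the list alone. Camera gave this list an adjusted p = 0.756, direction up against a median of -0.03 and a mean of 0.09. Bile acid genes had 4 of 18 higher and 3 lower, 5 and 4 adjusted over the list alone (camera adjusted p = 0.777, direction down, median -0.12, mean 0.03). The tricarboxylic acid cycle had 3 of 20 higher and 1 lower, 4 and 4 adjusted over the list alone (camera adjusted p = 0.777, direction down, median 0.02). ATF4 targets had 2 of 25 higher and 1 lower (camera adjusted p = 0.827, direction down, median 0.19, mean 0.53). Amino acid transporters had 1 of 17 higher and 1 lower (camera adjusted p = 0.825, direction up, median -0.08, mean -0.03), and both lists kept these counts adjusted over the list alone. Cytochrome P450 genes had 1 of 20 higher and 3 lower, as adjusted over the list alone (camera adjusted p = 0.245). Autophagy and lysosome genes had 1 of 18 higher and 1 lower, 2 and 1 adjusted over the list alone (camera adjusted p = 0.14). Periportal markers had 1 of 13 higher and 2 lower, 2 and 3 adjusted over the list alone (camera adjusted p = 0.143). Endothelial markers had 1 of 12 higher (camera adjusted p = 0.135), erythroid markers 1 of 6 lower (0.267) and cholangiocyte markers 1 of 6 lower (2 adjusted over the list alone; 0.678). By edgeR no gene was called in the circadian clock (19 tested; camera adjusted p = 0.56), cell cycle (19; 0.234), lymphocyte (12; 0.825), neutrophil (3; 0.245), adipocyte (1; 0.756) and mitochondrially encoded (13; 0.777) lists, over all genes or adjusted over the list alone.

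**Figure D3:**
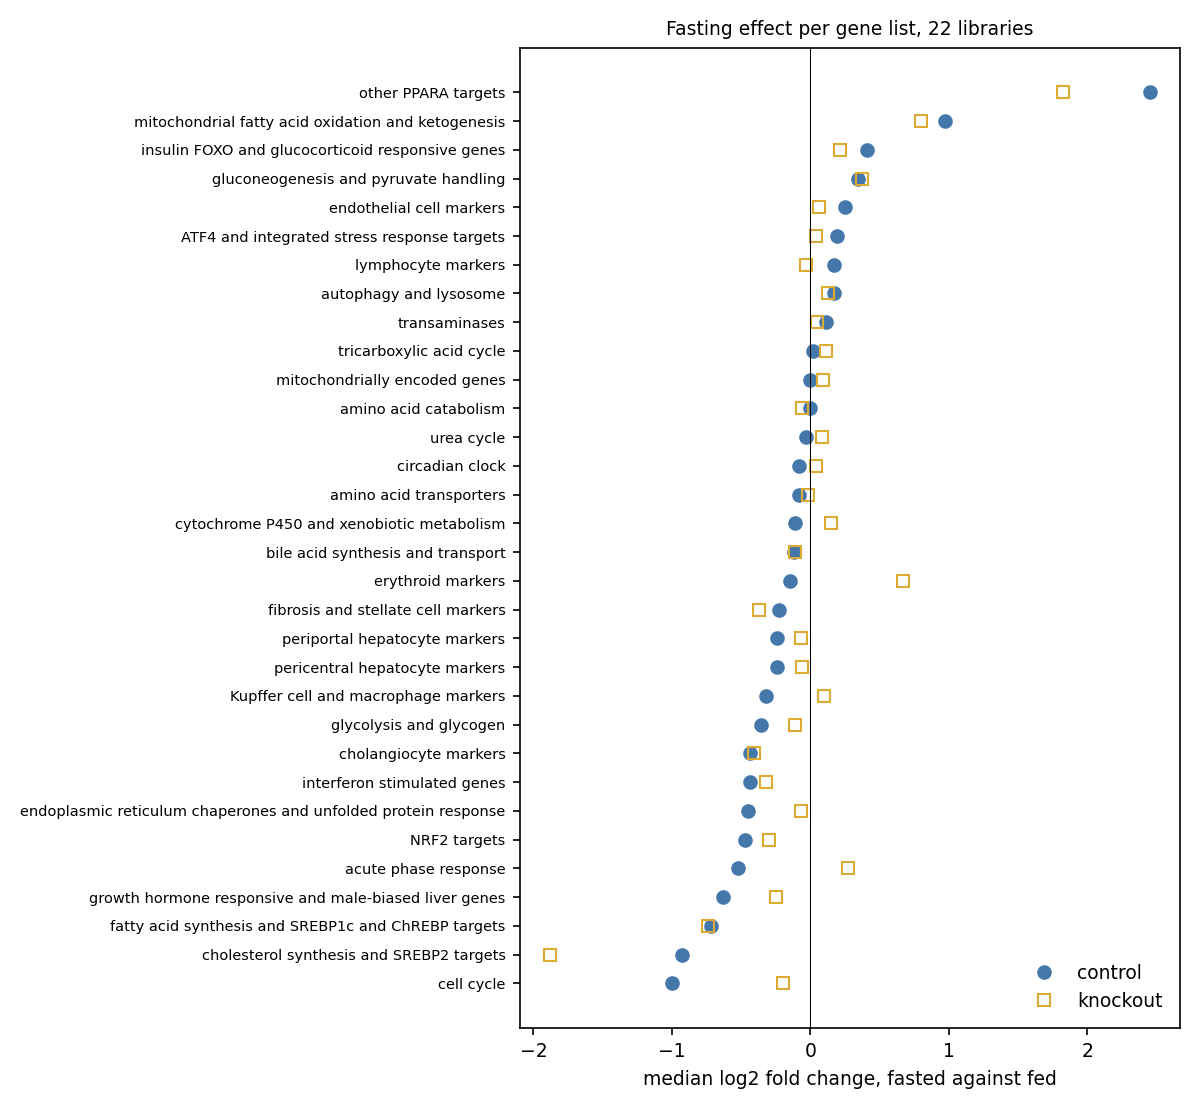
Median log2 fold change of fasted against fed livers (horizontal axis) over the tested genes of each list with at least 6 tested genes (vertical axis), in control mice (circles) and knockout mice (squares), over 22 libraries. Other PPARA targets lie at 2.45 and 1.82 and cholesterol synthesis at -0.93 and -1.88.

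In knockout mice fasting also raised fatty acid catabolism and lowered sterol and lipid synthesis. Cyp4a14 went from 200 ± 133 CPM to 5830 ± 1350 CPM (SD, n = 6 and n = 6; log2 4.86 ± 0.63 SE) and Cpt1a from 299 ± 30 to 753 ± 139 CPM (1.33 ± 0.13). Thrsp fell from 127 ± 50.2 to 18 ± 10.2 CPM (-2.81 ± 0.49) and Hsd3b5 from 171 ± 29.5 to 19.9 ± 13.5 CPM (-3.10 ± 0.49; SD, n = 6 and n = 6). Over 23 libraries edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 379 of 17055 genes, 185 higher and 194 lower. Over 22 libraries, without the library labelled control fasted replicate 4, it called 1029 of 16757 genes (483 higher, 546 lower), which included all 379. Of these 306 changed at least 2-fold (150 higher, 156 lower). By the same naming rule the greatest rises were in Cyp4a14, Cdkn1a (4.35 ± 0.93), a cyclin-dependent kinase inhibitor, Cyp4a31 (3.75 ± 0.42), Apoa4 (3.73 ± 0.62) and Cyp4a10. The call of Cdkn1a ended with limma voom with sample weights, title-number clusters as a block or only the groups compared (adjusted p = 0.0502 to 0.15 after Benjamini-Hochberg adjustment). The greatest falls were in Hsd3b5, Cyp2c55 (-2.87 ± 0.46), Thrsp, Fdps (-2.80 ± 0.58), of the mevalonate pathway, and Gstm3 (-2.67 ± 0.29). With library totals in place of TMM factors 36.7% of the calls over 22 libraries were higher, against 46.9%.

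Of the 24 other PPARA targets 19 rose in knockout livers (21 adjusted over the list alone), with a median of 1.82, among them Crat (2.04 ± 0.20), Pex11a (1.56 ± 0.18) and Ehhadh (3.02 ± 0.30). In mitochondrial fatty acid oxidation and ketogenesis 15 of 19 genes rose and none fell (17 and 1 adjusted over the list alone; median 0.80), including Slc25a20 (1.12 ± 0.10) and Acadm (1.12 ± 0.11). Of 24 cholesterol synthesis genes 18 fell (22 adjusted over the list alone; median -1.88), including Ebp (-0.77 ± 0.11), Sc5d (-1.61 ± 0.22), Pmvk (-2.04 ± 0.27) and Dhcr7 (-1.96 ± 0.29). In fatty acid synthesis 10 of 22 genes fell and 1 rose (12 and 2 adjusted over the list alone; median -0.74), with Acly (-1.64 ± 0.13), Acss2 (-2.24 ± 0.22) and Slc25a1 (-0.75 ± 0.10) lower and Elovl5 higher (1.09 ± 0.13). These 4 lists passed camera (adjusted p = 4.58e-40, 2.54e-31, 1.75e-34 and 3.8e-13) and kept their call with an estimated correlation (adjusted p = 0.0003, 0.00369, 0.039 and 0.00526). Of 18 genes of gluconeogenesis and pyruvate handling 6 were higher and none lower, 9 adjusted over the list alone (camera adjusted p = 5.16e-06; adjusted p = 0.0524 with an estimated correlation). Among them were Pcx (0.85 ± 0.13), Slc37a4 (0.97 ± 0.15) and Eno1 (0.66 ± 0.16). Growth hormone responsive genes also passed camera, with 5 of 18 lower, and 7 lower and 2 higher adjusted over the list alone (adjusted p = 0.000643). So did interferon stimulated genes, with 2 of 22 lower, 3 adjusted over the list alone (adjusted p = 0.000643). Insulin, FOXO and glucocorticoid responsive genes had 4 of 22 higher, and 4 higher and 1 lower adjusted over the list alone, and fibrosis and stellate markers 1 of 14 lower by either count (camera adjusted p = 0.0375 for both). With an estimated correlation these 4 lists did not pass (adjusted p = 0.251, 0.251, 0.518 and 0.306).

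Transaminases in knockout livers had 2 of 14 higher and 2 lower with fasting, 3 and 3 adjusted over the list alone (camera adjusted p = 0.966, direction down, median 0.05, mean 0.15). Gpt2 was higher by 0.88 ± 0.18, and Kyat1 (-0.82 ± 0.12) and Agxt (-0.50 ± 0.13) were lower. In amino acid catabolism 3 of 29 genes were higher and 5 lower, 5 and 7 adjusted over the list alone (camera adjusted p = 0.325). Mat1a rose by 1.61 ± 0.12 and Tdo2 by 0.46 ± 0.11, and Ido2 (-0.98 ± 0.12) and Aldh4a1 (-0.63 ± 0.12) fell. Urea cycle genes had 3 of 8 higher and 1 lower, as adjusted over the list alone (camera adjusted p = 0.13), with Asl at 1.24 ± 0.19, Slc25a13 at 0.56 ± 0.09, Arg1 at 0.40 ± 0.12 and Otc at -0.51 ± 0.11.

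The fasting effects of the genotypes, which share no library, were compared across genes. Over the 9538 genes with a mean log2 CPM of at least 2 in the 22 libraries, the log2 fold changes correlated with Pearson r = 0.745 and Spearman rho = 0.627, a correlation across genes, which are not independent replicates. Over all 16757 genes they were 0.307 and 0.362, and over the 17055 genes of the 23 libraries 0.233 and 0.302. In the 22 libraries 335 genes rose and 356 fell in both genotypes, against 19.3 and 22.5 for independent lists, and none was called in opposite directions. Of the 1360 genes called in control mice 1312 had the same sign in knockout mice.

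**Figure D4:**
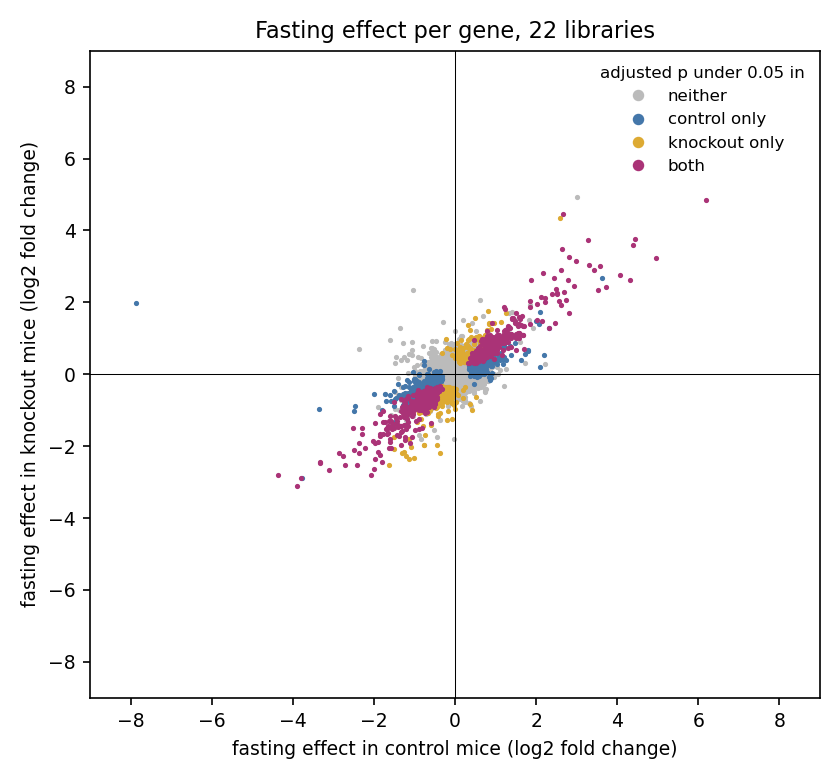
Log2 fold change of fasted against fed livers in control mice (horizontal axis) and knockout mice (vertical axis) for genes with a mean log2 CPM of at least 2, over 22 libraries; each point is a gene, coloured by where its adjusted p was under 0.05. Pearson r is 0.745 across the 9538 genes, and the single point at -7.88 on the horizontal axis is Dmbt1.

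Zfp871, a zinc finger gene, was the gene whose response to fasting differed between genotypes over 22 libraries, by the interaction test. It stood at 18.9 ± 5.13 CPM in control fed (n = 5) and 25.4 ± 3.89 in control fasted livers (n = 5), and at 33.1 ± 5.6 in knockout fed (n = 6) and 16.7 ± 3.99 CPM in knockout fasted livers (SD, n = 6). Its interaction was -1.42 ± 0.25 (log2, SE; adjusted p = 0.0284 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was the 1 gene called, with 786 genes at an unadjusted p under 0.05, fewer than the 838 that chance gives, and DESeq2 called 10. Its call ended in 13 of the 22 fits that leave out a library, namely control fed replicates 1, 3, 4 and 5, control fasted 1 and 6, knockout fed 1, 4 and 5 and knockout fasted 1, 3, 4 and 6, which left 0 genes called. The adjusted p of Zfp871 was then 0.0515 to 0.112 by the same edgeR test and Benjamini-Hochberg adjustment. Over 23 libraries edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 17055 genes, with 964 at an unadjusted p under 0.05 where chance gives 853. DESeq2 called 22 and limma voom with sample weights 1, and edgeR called 1 without control fed replicate 2. The median interaction of all genes over 23 libraries was -0.04 with TMM factors and -0.24 with library totals. The next genes by p over 22 libraries did not pass: Fmn1 (-1.83 ± 0.42), 4932438A13Rik (-0.74 ± 0.17), and Colgalt2 and Gm22036, which had 3 and 2 reads in all in a group and for which no fold is given. Their adjusted p was 0.21 or more by edgeR with Benjamini-Hochberg adjustment. Over 23 libraries Zfp871 (-1.40 ± 0.25), Dll4 (-2.15 ± 0.49), Lnpep (-1.75 ± 0.41), Gm15441 and Gm17149 had the smallest p and did not pass. The interaction of Gpt2 itself was -0.03 ± 0.27 and that of Gpt 0.40 ± 0.18 over 22 libraries, neither of which passed.

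By camera at the preset correlation 11 lists passed the interaction test over 22 libraries and 16 over 23 libraries. With an estimated correlation none passed in either fit (adjusted p = 0.368 to 0.6 for the 11), and by edgeR no single gene of the lists given here passed over all genes. In the knockout the response lay higher for the acute phase, with a median difference of 0.45 and 3 of 22 genes adjusted over the list alone (camera adjusted p = 1.26e-08). Its leading members were Orm1 at 0.75 ± 0.19, Orm2 at 1.11 ± 0.31 and Socs3 at 1.58 ± 0.52. It lay higher also for endoplasmic reticulum chaperones (median 0.42, 1 of 20 adjusted over the list alone; camera adjusted p = 1.85e-07), with Dnajb9 at 0.93 ± 0.27. It lay lower for cholesterol synthesis (median -0.85, 23 of 24 negative; camera adjusted p = 3.4e-05). It lay lower for other PPARA targets (median -0.42, 1 of 24 adjusted over the list alone; camera adjusted p = 6.74e-05), where Acot4 was at -1.05 ± 0.27 and Acot1 at -1.33 ± 0.47. In the mean log2 CPM of a list, knockout minus control was 0.49 in fed and -0.18 in fasted livers for cholesterol synthesis. It was 0.42 and -0.14 for other PPARA targets, so for both lists the genotypes differed more when fed. For the acute phase it was -0.29 and 0.28, and for the chaperones -0.12 and 0.26.

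Averaged over feeding states, knockout livers had less Gpt2 and more of 5 other genes, Cdh5 and Kdr of the endothelial list among them. Msn, moesin, which links membrane to actin, stood at 10.7 ± 1.47 and 10.8 ± 0.715 CPM in control fed and fasted livers (SD, n = 5 and n = 5). In knockout livers it stood at 19.3 ± 4.21 and 18.7 ± 4.66 CPM (SD, n = 6 and n = 6), higher by a log2 difference of 0.82 ± 0.12 (adjusted p = 0.000873, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mrc1, the mannose receptor of macrophages and sinusoidal endothelium, was higher by 0.76 ± 0.13 (adjusted p = 0.013 by the same edgeR test). The endothelial genes Cdh5, VE-cadherin, and Kdr, a VEGF receptor, were higher by 0.75 ± 0.14 and 0.59 ± 0.11 (adjusted p = 0.0288 for both, edgeR with Benjamini-Hochberg adjustment). Gpt2 was lower by a log2 difference of -2.63 ± 0.14 (adjusted p = 6.27e-12). Gh, growth hormone, had no read in any of the 11 control libraries and between 8 and 97 reads in 9 of the 12 knockout libraries (adjusted p = 0.0288, edgeR with Benjamini-Hochberg adjustment).

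These were the 6 of 16757 genes called over 22 libraries by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. An unadjusted p under 0.05 was reached there by 1459 genes, more than the 838 that chance gives. Over 23 libraries the same edgeR test called 1 of 17055 genes, Gpt2 (-2.51 ± 0.31 SE, adjusted p = 0.000928), and 1340 genes had an unadjusted p under 0.05 where chance gives 853. Kdr, Gh, Col14a1 (0.63 ± 0.14) and Rab10 (0.32 ± 0.07) followed without passing (adjusted p = 0.222 to 0.365), and 4 genes were called without knockout fasted replicate 1. Over 22 libraries Gpt2, Msn and Mrc1 kept their call without any single library. Those of Cdh5 and Kdr ended without control fed replicate 2 or 3, control fasted 3 or 6, knockout fed 1, 3 or 4 or knockout fasted 2 or 6, which left 3 genes called. That of Cdh5 ended also without control fasted 5, and that of Kdr without control fasted 2 or knockout fed 6, with an edgeR adjusted p of 0.0508 to 0.0924 after Benjamini-Hochberg adjustment. The call of Gh ended without control fed 2 or 3, control fasted 2, 3, 5 or 6, knockout fed 1, 3, 4 or 6 or knockout fasted 2, 3 or 6 (adjusted p = 0.0508 to 0.0917, edgeR with Benjamini-Hochberg adjustment). With title-number clusters as a random block, and with limma voom with sample weights, 2 of the 6 kept their call, Gpt2 and Msn. Mrc1, Cdh5 and Kdr then had an adjusted p = 0.145 with the block and 0.0584, 0.0799 and 0.0872 with the weights (limma with Benjamini-Hochberg adjustment). Cdh5 and Kdr did not pass either with a mean CPM of at least 1 (adjusted p = 0.0566 for both, edgeR with Benjamini-Hochberg adjustment). The count rose to 10 without control fed replicate 4 and to 15 without knockout fasted replicate 1. It was 12 with library totals, 12 with no filter beyond 1 count and 39 with DESeq2.

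Endothelial and macrophage markers were higher in knockout livers as lists, averaged over feeding states, by camera at the preset correlation. Within fed mice the macrophage markers did not pass camera. In the mean log2 CPM of the list, knockout minus control was 0.25 in fed and 0.61 in fasted livers for macrophage markers. This gap between feeding states did not pass (exact permutation p = 0.258). For endothelial markers it was 0.51 in fed and 0.37 in fasted livers. Of 12 endothelial cell markers 2 were higher over 22 libraries and 9 adjusted over the list alone, with 11 positive and a median of 0.49. Besides Kdr and Cdh5, Ptprb stood at 0.50 ± 0.12 and Oit3 at 0.65 ± 0.17. Of 13 Kupffer cell and macrophage markers none was called over all genes and 8 were higher adjusted over the list alone, with all 13 positive and a median of 0.51. Their leading members were C1qc (0.51 ± 0.11), C1qb (0.55 ± 0.13), Timd4 (1.01 ± 0.25) and Cd5l (0.54 ± 0.14). Both lists passed camera (adjusted p = 6.87e-10 and 4.25e-08) and neither did with an estimated correlation (adjusted p = 0.255 and 0.415). By limma's fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, adjusted p = 0.0413 for the endothelial and 0.12 for the macrophage list. Over 23 libraries 9 lists passed camera for this comparison, these 2 among them (adjusted p = 1.28e-08 and 2.3e-08), and none passed with an estimated correlation. Fibrosis and stellate cell markers had a median of 0.20 and a mean of -0.02, with 0 of 14 called by edgeR and 1 adjusted over the list alone (camera adjusted p = 0.0773). Among metabolic lists, transaminases had only Gpt2 called of 14, by either count (camera adjusted p = 0.0773). Gluconeogenesis and pyruvate handling had 0 of 18 called (median -0.02; camera adjusted p = 0.44) and amino acid catabolism 0 of 29 (median 0.00; 0.567), by either count. The urea cycle had 0 of 8 called (median 0.01; camera adjusted p = 0.657), with Slc25a13 at 0.21 ± 0.07 called when adjusted over the list alone.

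**Figure D5:**
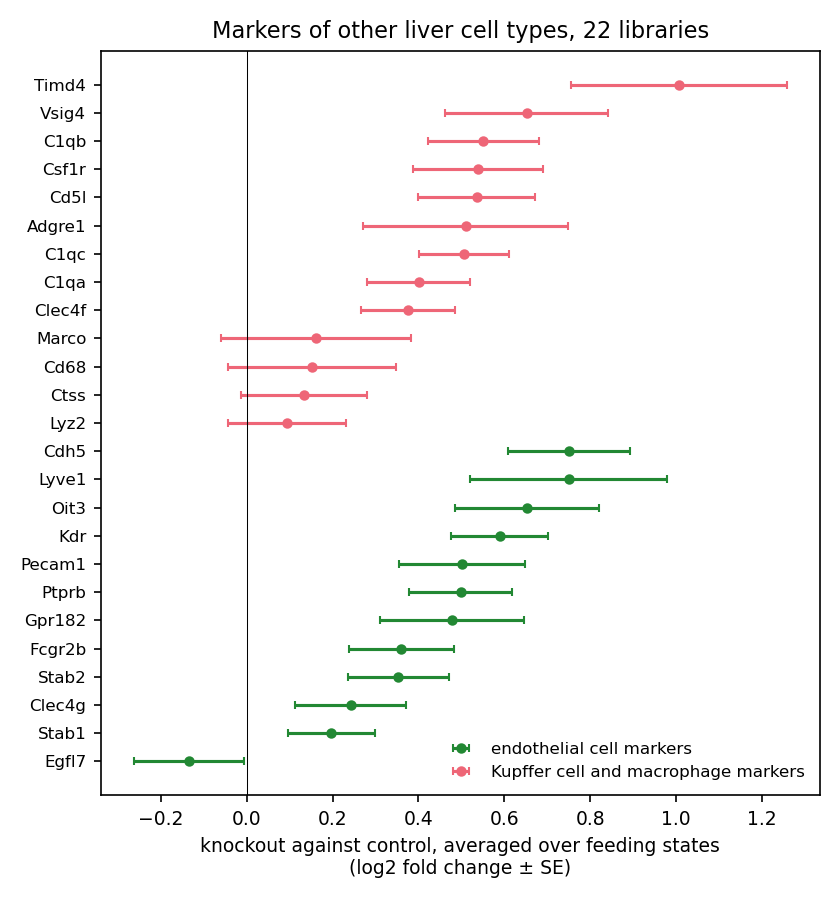
Log2 fold change of knockout against control livers averaged over feeding states (horizontal axis; point and bar are estimate ± SE) for the 12 endothelial and 13 Kupffer cell and macrophage markers (vertical axis), over 22 libraries. Of the endothelial markers 11 are positive, as are all 13 macrophage markers; Timd4 is at 1.01 and Egfl7 at -0.13.

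Within fed mice Gpt2 was again the gene that stood apart between genotypes, at -2.62 ± 0.19 (log2, SE; n = 5 and n = 6; adjusted p = 1.55e-08 by edgeR with Benjamini-Hochberg adjustment). It was the 1 gene of 16757 called over 22 libraries, although 1509 genes had an unadjusted p under 0.05, more than the 838 that chance gives. DESeq2 called 83. Over 23 libraries edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 17055 genes (Gpt2 -2.62 ± 0.44, adjusted p = 0.116), with 1074 at an unadjusted p under 0.05 where chance gives 853. DESeq2 then called 32 and limma voom with sample weights 1. The count over 22 libraries became 13 without control fed replicate 4, 8 without knockout fed 4, 5 without control fed 2 and 3 without knockout fasted 6. It became 2 without control fasted 5, knockout fed 2 or knockout fasted 1, 2 or 4. With library totals in place of TMM factors it was 5, of which 80% were higher. The next genes by p did not pass: Kdr (0.87 ± 0.16), Orm2 (-1.10 ± 0.22), Msn (0.85 ± 0.17) and Slc4a4 (0.58 ± 0.12), and over 23 libraries Kdr, Dll4 (1.79 ± 0.37), Acot5, with 1 read in all in control fed livers, and Zfp871 (0.81 ± 0.18). In the list tests over 22 libraries 7 lists passed camera at the preset correlation and none with an estimated correlation (lowest adjusted p = 0.494). By the former endothelial markers were higher in the knockout (median 0.56, 7 of 12 adjusted over the list alone; camera adjusted p = 3.72e-06). So were cholesterol synthesis genes (median 0.45, 23 of 24 positive; camera adjusted p = 3.78e-06) and other PPARA targets (0.27, 2 of 24 adjusted over the list alone; 0.023). The acute phase response was lower (median -0.16, 3 of 22 adjusted over the list alone; camera adjusted p = 0.000148). So were the tricarboxylic acid cycle (median -0.07; camera adjusted p = 0.0161), endoplasmic reticulum chaperones (-0.12; 0.0419) and growth hormone responsive genes (-0.27; 0.0486). Over 23 libraries endothelial markers, cholesterol synthesis, other PPARA targets and the tricarboxylic acid cycle passed camera, and none with an estimated correlation.

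Within fasted mice Gpt2 was lower in the knockout by a log2 difference of -2.64 ± 0.19 (SE; n = 5 and n = 6) over 22 libraries. Gpt2 was the 1 gene of 16757 called by edgeR (adjusted p = 1.23e-08 after Benjamini-Hochberg adjustment), with 672 genes at an unadjusted p under 0.05, fewer than the 838 that chance gives, and DESeq2 called 2. With the library labelled control fasted replicate 4 edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 17055 genes (Gpt2 -2.40 ± 0.43, adjusted p = 0.24). An unadjusted p under 0.05 was then reached by 1164 genes, where chance gives 853. DESeq2 then called 9 and limma voom with sample weights 1, and the median log2 fold change of all genes was -0.03 with TMM factors and -0.19 with library totals. The next genes by p did not pass: Msn (0.79 ± 0.17), Hmox1 (1.25 ± 0.29), Il13ra1 (1.06 ± 0.24) and Colgalt2, with 3 reads in all in control fasted livers. With the doubted library they were Aifm3 (-1.11 ± 0.24), Mettl27 (-0.71 ± 0.16), Slc34a1 (-12.48 ± 2.83) and Col14a1 (0.80 ± 0.19). Over 22 libraries 11 lists passed camera at the preset correlation and none with an estimated correlation (lowest adjusted p = 0.272, for the macrophage markers). All 13 Kupffer cell and macrophage markers were positive, with a median of 0.60 and 8 called when adjusted over the list alone (camera adjusted p = 1.68e-11). They were led by C1qc (0.60 ± 0.15), Cd5l (0.80 ± 0.19), Csf1r (0.85 ± 0.22) and Timd4 (1.32 ± 0.36). Endothelial markers (median 0.36, 1 of 12 adjusted over the list alone; camera adjusted p = 3.07e-06), endoplasmic reticulum chaperones (0.29, 1 of 20; 3.79e-06) and the acute phase response (0.31, 0 of 22; 0.000244) were also higher by camera. The same held for glycolysis and glycogen (median 0.21, 1 of 17 adjusted over the list alone; camera adjusted p = 0.00155), erythroid markers (0.39; 0.00721), interferon stimulated genes (0.19; 0.0364) and stellate markers (0.13, with a mean of -0.05; 0.0375). Other PPARA targets (median -0.14; camera adjusted p = 0.00731), mitochondrial fatty acid oxidation (-0.08; 0.032) and transaminases (-0.09; 0.0349) were lower. The transaminase list holds the targeted Gpt2 itself and was not tested without it, so its result does not show that the other transaminases were lower. Over 23 libraries 16 lists passed camera, and none with an estimated correlation.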

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

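The tests of kidney, mixture and swap were chosen after the results they examine were seen, as was the fit of 22 libraries, whereas the comparison of each library with its group and the interaction tests were planned.

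In the library labelled control fasted replicate 4 the kidney genes stood far above every other library: the median of 17 kidney genes, none of them in the 35 lists, was 10.35 log2 CPM, 11.33 above the highest of the other 22 libraries, with Kap at 7040, Slc34a1 at 4420 and Umod at 3450 CPM by library totals, and none of the 17 above 8.88 CPM in another library. Genes of heart, skeletal muscle, lung, small intestine, spleen, brain and white adipose tissue lay at most 0.31 above the highest other library. The median of 15 liver genes was 4.28 log2 CPM, against 11.64 to 12.07 elsewhere, and they stood at a median of 0.375% of their level in the other libraries (Alb 0.189%, Cyp2e1 17.6%), which argues against liver RNA mixed with RNA of another tissue at the share of 10% or more that was set as the bound. Among the other 22 libraries 0 had kidney genes at this level or Gpt2 against the label, which argues against a swap within them, while control fed replicate 6 could not be examined beyond chromosome 1. RNA of kidney in place of liver may account for the profile, as a hypothesis found and tested on the same data, and no biological explanation was tested.

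The same library stood apart from its group in genes with a read (20400), mitochondrial share (7.9%), TMM factor (1.67), Gpt2 (33.8 CPM), Gpt (21.2 CPM) and Kap (4350 CPM). Among the other libraries, control fasted replicate 2 stood apart in total reads (19.9 M), knockout fed 3 in the share of the 20 most abundant genes (40.4%) and TMM factor (0.914), and knockout fasted 2 in mitochondrial share (6.87%). For single genes, control fed 5 stood apart in Gpt (509 CPM) and Fgf21 (0.167 CPM), control fed 1 in Kap (0.404 CPM), knockout fed 3 in Msn (27.5 CPM) and knockout fasted 4 in Fgf21 (15.4 CPM). Over 36 groups of values, those of the library measures and of Gpt2, Gpt, Alb and Kap in 23 libraries, 12 values stood apart, and over 72 groups of levels of 18 other genes in 22 libraries 3 did, where chance gives about 1 in 20 groups.

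The response to fasting differed between genotypes over 22 libraries in Zfp871, by -1.42 ± 0.25 (log2, SE; adjusted p = 0.0284, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The call ended without control fed replicate 1, 3, 4 or 5, control fasted 1 or 6, knockout fed 1, 4 or 5 or knockout fasted 1, 3, 4 or 6 (adjusted p = 0.0515 to 0.112 by the same edgeR test). By camera at the preset correlation 11 lists passed the same test, and with an estimated correlation none of the 11 did (adjusted p = 0.368 to 0.6). In the knockout it lay higher for glycolysis and glycogen (median 0.15, 15 of 17 positive; adjusted p = 0.000983), the tricarboxylic acid cycle (0.10, 16 of 20; 0.0213), the acute phase response (0.45, 18 of 22; 1.26e-08), NRF2 targets (0.30, 11 of 15; 0.0119) and endoplasmic reticulum chaperones (0.42, 19 of 20; 1.85e-07). It lay higher also for periportal markers (0.14, 13 of 13; 0.0213), Kupffer cell and macrophage markers (0.37, 13 of 13; 0.00176) and erythroid markers (0.79, 6 of 6; 0.000914). It lay lower for mitochondrial fatty acid oxidation (-0.17, 4 of 19 positive; 0.00458), other PPARA targets (-0.42, 9 of 24; 6.74e-05) and cholesterol synthesis (-0.85, 1 of 24; 3.4e-05). In exact permutations of the list scores within feeding states, chosen after these results were seen, none of 35 lists did (lowest adjusted p = 0.515; acute phase permutation p = 0.0365).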

How the results depend on the processing

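The alternatives over 23 libraries were planned, and those over the 22 libraries without the library labelled control fasted replicate 4 were chosen after the data were seen. Where a count or call changed and no reason is given, the cause was not tested. The direction of Gpt2 held under every alternative run, from -2.74 to -2.251 with each library left out. In fasted mice over 23 libraries Gpt2 stood at -2.004 with title-number clusters as a random block (adjusted p = 0.63, limma with Benjamini-Hochberg adjustment).

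Over 23 libraries, the number of genes called for the genotype effect in fed mice (0) became 1 with library totals, 32 with DESeq2, 1 with limma voom with sample weights and 1 with only the groups compared. In fasted mice (0) it became 1 with library totals, 9 with DESeq2 and 1 with voom weights. The averaged effect (1) became 21 with DESeq2. Fasting in control mice (805) became 1318 with DESeq2 and 258 with only the groups compared. That fit held the doubted library, and without this library it called 1248. Fasting in knockout mice (379) became 680 with DESeq2, 1166 with voom weights and 1020 with only the groups compared, a fit that leaves out the doubted library. The interaction (0) became 22 with DESeq2 and 1 with voom weights. Gpt2 passed in fed mice with library totals (-2.567, adjusted p = 0.0214), DESeq2 (-2.621, 6.6e-07), voom weights (-2.659, 9.1e-09) and only the groups compared (-2.617, 6.28e-12), and in fasted mice with library totals (-2.397, 0.0371), DESeq2 (-2.406, 5.33e-06) and voom weights (-2.559, 8.53e-09), each with Benjamini-Hochberg adjustment.

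Over 22 libraries the genotype effect in fed mice (1) became 5 with library totals, 14 with no filter beyond 1 count, 83 with DESeq2 and 2 with mitochondrial and the 20 most abundant genes left out, and in fasted mice (1) 2 with DESeq2. The averaged effect (6) became 12 with library totals, 12 with no filter, 3 with a mean CPM of at least 1, 39 with DESeq2, 2 with voom weights and 2 with title-number clusters as a random block. The interaction (1) became 10 with DESeq2.

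The correlation of the fasting effects (0.233 over 23 libraries) was 0.062 with no filter, 0.283 with a mean CPM of at least 1, 0.077 with DESeq2, 0.349 with voom weights, 0.302 with title-number clusters as a block and 0.485 over genes with a mean log2 CPM of at least 2. Over 22 libraries (0.307) it was 0.064 with no filter, 0.647 with a mean CPM of at least 1, 0.056 with DESeq2, 0.356 with voom weights and 0.745 over genes with a mean log2 CPM of at least 2. With an estimated correlation the lists that passed camera numbered 0, 0, 0, 2, 5 and 0 over 23 libraries (genotype fed, fasted and averaged, fasting in control and knockout, interaction), against 4, 16, 9, 21, 11 and 16, and 0, 0, 0, 4, 4 and 0 over 22. With library totals 15 passed for the averaged effect over 23 libraries. Slc34a1 turned to -0.545 with voom weights (adjusted p = 0.898, limma), and Dmbt1 to 1.206 without control fed replicate 3 (23 libraries) and 1.477 (22 libraries).

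With each library left out, the counts over 23 libraries ranged from 0 to 1 (fed), 0 to 1 (fasted), 1 to 6 (averaged), 530 to 1360 (fasting in control), 277 to 1029 (fasting in knockout) and 0 to 1 (interaction). Over 22 they ranged from 1 to 13, 1 to 1, 3 to 15, 1088 to 1434, 845 to 1075 and 0 to 1. The correlation of the fasting effects ranged from 0.18 to 0.307 and from 0.241 to 0.315. Gpt2 ranged from -2.694 to -2.538 in fed mice (highest adjusted p = 0.523, edgeR), -2.642 to -2.251 in fasted mice (0.82) and -2.628 to -2.433 averaged (0.00401). Over 22 libraries it ranged from -2.701 to -2.538 (3.35e-07), -2.74 to -2.496 (4.16e-07) and -2.677 to -2.555 (3.7e-10). Slc34a1 ranged from 1.783 to 11.736, Dmbt1 from -8.875 to 1.206 and from -8.404 to 1.477, and Zfp871 from -1.548 to -1.268 and from -1.567 to -1.291. Of the named genes called over 22 libraries, 59 of 69 kept their call without any single library for fasting in control mice and 39 of 42 in knockout mice; over 23 libraries 39 of 66 and 32 of 36 did. No paired analysis was possible because the labels give the groups no shared replicate numbers. The clusters of nearly consecutive title numbers, whose meaning the labels do not give, could be fitted as a random block, with the changes given above and a consensus correlation of -0.065 over 23 and -0.013 over 22 libraries. Some clusters hold knockout libraries only and some control libraries only, and within these genotype and cluster cannot be told apart. In the simulated data most 1.5-fold changes were left uncalled (26.9% recovered for the genotype effect in fed mice).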

Other observations

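The fit of 22 libraries, the permutation tests of list scores, the matched random lists and the tests of hepatocyte share, pituitary RNA and a transgene were chosen after the results they examine were seen, although the bound for the matched lists was set before their own result, and the splits of the samples were planned.

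The lists of bile acid genes, amino acid transporters, ATF4 targets and periportal markers did not pass camera over 22 libraries for fasting in control (adjusted p = 0.777, 0.825, 0.827 and 0.143) or knockout livers (0.423, 0.423, 0.423 and 0.966). The single genes given here, from these and other lists, were picked among the named genes after their values were seen because they passed in both genotypes. Abcb11, the bile salt export pump, fell by 1.26 ± 0.14 in control and by 1.20 ± 0.12 in knockout livers (log2, SE; n = 5 and n = 5, n = 6 and n = 6), and Cyp8b1, the sterol 12-hydroxylase of bile acid synthesis, rose in both, by 0.67 ± 0.18 in knockout livers (adjusted p = 1.18e-05 in control and 0.0207 in knockout, edgeR with Benjamini-Hochberg adjustment). Cdh1, E-cadherin of periportal hepatocytes, fell (-1.51 ± 0.21 and -0.76 ± 0.19), and Hsd17b13, a lipid droplet protein, rose (0.70 ± 0.14 and 0.83 ± 0.13). Cyp2c29, a cytochrome P450, fell (-1.91 ± 0.20 and -1.88 ± 0.18). Slc25a22, a mitochondrial glutamate carrier, rose (1.07 ± 0.16 and 0.82 ± 0.15), and Slc38a3, a glutamine transporter, fell (-0.68 ± 0.15 and -0.61 ± 0.14). Atf5, a transcription factor of the stress response, rose (1.30 ± 0.15 and 0.90 ± 0.13), and Fgf21, a hormone of the fasted liver, went from 0.0384 ± 0.0728 to 4.63 ± 2.58 CPM in control livers (SD, n = 5 and n = 5) and from 0.291 ± 0.321 to 5.21 ± 5.32 CPM in knockout livers (SD, n = 6 and n = 6). The metallothionein gene Mt1 rose by 2.25 ± 0.54 in knockout livers, and its value in control livers, chosen after it was seen, was 2.52 ± 0.60. Map1lc3a of autophagy rose by 0.89 ± 0.15 and 0.50 ± 0.13, Lyve1 of sinusoidal endothelium by 1.28 ± 0.34 in control livers and also in knockout livers (adjusted p = 0.0449, edgeR with Benjamini-Hochberg adjustment), and Alas2 of haem synthesis was lower (-0.76 ± 0.14 and -0.47 ± 0.13). Each of these passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in both genotypes and none passed the interaction test (the lowest adjusted p was 0.977). Picking genes that passed in both genotypes works against finding an interaction, and the simulation recovered 17.9% of 2-fold interactions. The interaction result therefore does not show that these responses were equal.

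Further lists did not pass camera for fasting in knockout mice over 22 libraries. The numbers higher and lower were 4 and 0 of 22 acute phase genes (7 and 0 adjusted over the list alone; camera adjusted p = 0.128), 4 and 1 of 20 in the tricarboxylic acid cycle (5 and 1; 0.134), 1 and 4 of 15 NRF2 targets (2 and 5; 0.067), 3 and 4 of 18 bile acid genes (4 and 4; 0.423) and 2 and 0 of 25 ATF4 targets (2 and 1; 0.423). They were 1 and 2 of 17 amino acid transporters (the same; 0.423), 2 and 1 of 17 glycolysis genes (the same; 0.84), 2 and 2 of 20 cytochrome P450 genes (the same; 0.77), 3 and 1 of 13 periportal markers (3 and 3; 0.966) and 0 and 2 of 12 pericentral markers (the same; 0.0945).

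Endothelial and Kupffer cell markers, none of which stood in another list, lay higher in knockout livers over 22 libraries by camera at the preset correlation and not with an estimated correlation (adjusted p = 0.255 and 0.415). As list scores the endothelial markers differed by 0.44 (12 of 12 knockout libraries above the control median; exact permutation p = 0.000492, adjusted over 35 lists p = 0.0172), while the macrophage markers did not pass (0.43, 11 of 12; exact permutation p = 0.00344, adjusted p = 0.0602). A trend with transcript length and GC content was present over 9509 genes (Spearman 0.29 and -0.3 across genes), yet each list's median lay at percentile 100 of 10000 random lists matched on level, length and GC content (0.49 against -0.08 to 0.10, and 0.51 against -0.15 to 0.05), which argues against it as the whole cause. A lower share of hepatocytes would raise the markers of every other cell type alike and stays open: the endothelial and macrophage score exceeded that of stellate markers by 0.34 (exact permutation p = 0.00319), but these lists were picked for their difference, and over all 6 non-hepatocyte lists with at least 6 tested genes the differences did not move apart past the threshold (exact permutation p = 0.097), with stellate markers at 0.09 (exact permutation p = 0.294; higher within fasted mice by camera, adjusted p = 0.0375, and adjusted p = 0.565 with an estimated correlation), cholangiocyte markers at -0.04 (exact permutation p = 0.906) and lymphocyte markers at 0.39 (11 of 12; exact permutation p = 0.0704, not passing before or after adjustment). Erythroid markers, also among these lists, were at 0.12 (7 of 12; exact permutation p = 0.52). More endothelial cells and macrophages, or more of their transcripts per cell, were not tested and stay open too.

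Gh, growth hormone, had 354 reads over 9 of 12 knockout libraries and none over 11 control libraries. RNA of pituitary cells was examined through 6 other pituitary hormone genes, which together had 118 reads in the knockout libraries. This was above the bound, relative to Gh, under which pituitary RNA would have been excluded. The reads of these genes in control libraries were not compared, so the value cannot decide and pituitary RNA stays open. Whether a growth hormone sequence carried by a transgene of the knockout mice was the source stays open too: Fisher's exact p = 0.000337 of Gh reads by genotype restates the difference for which Gh was noticed, the labels name no transgene, and 3 knockout libraries had no Gh read.

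Whether chance can be excluded was asked of each count of called genes with 100 splits of the same libraries, the real one included. Over 23 libraries it can be excluded for the averaged genotype effect (1 gene, highest other split 1, 3 splits as large), for fasting in control mice (805, highest other 654, 1 split) and for fasting in knockout mice (379, highest other 1, 1 split). For the genotype effect in fed mice (highest other 1), in fasted mice (highest other 13) and the interaction (highest other 1) the real count was 0, which all 100 splits reach whatever they call, so the comparison could not have excluded chance and says nothing on it. Over 22 libraries it can be excluded for the averaged genotype effect (6, highest other 28, 2 splits), fasting in control mice (1360, highest other 6, 1 split) and fasting in knockout mice (1029, highest other 311, 1 split), and it cannot for the number called for the genotype effect in fed mice (1, highest other 3, 10 splits), in fasted mice (1, highest other 34, 11 splits) and the interaction (1, highest other 12, 8 splits). In fed and in fasted mice the gene called was the targeted Gpt2, for which chance is excluded by its own exact permutation test (p = 0.00216 in each). Gpt2 was also the 1 gene of the averaged effect over 23 libraries and is among its 6 over 22. The splits therefore do not exclude chance for the other genes called in the averaged effect. The splits that called 28, 34 and 12 genes over 22 libraries exceeded the real counts several times. Whether a structure of the samples lies behind them was not tested, and none was identified. For the clusters of title numbers the consensus correlation was -0.013.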
